A study of Homo sapiens with 16 samples.

How the data were processed

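RNA was sequenced from U2OS cells, a human osteosarcoma line with wild-type p53. Per the labels, cells were transfected with a non-targeting siRNA (siNT) or an siRNA against SETD2 (siSETD2) and collected 48 h later. For the last 4 h they were left untreated or given 2 mM hydroxyurea (HU), 2 µM VE-822, or both. SETD2 is the histone methyltransferase that trimethylates lysine 36 of histone H3 (H3K36me3). HU inhibits ribonucleotide reductase, lowers the supply of deoxynucleotides and stalls replication forks, and VE-822 inhibits the checkpoint kinase ATR. These 8 groups held 2 libraries each, numbered R1 and R2 in the labels, which makes 16 libraries. The labels do not say that R1 and R2 were separate cultures, so every p-value measures only the spread between these libraries, which may be technical.

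One table of FPKM values (fragments scaled to exon length and library depth) for 58735 Ensembl genes and 16 libraries was deposited by the authors, with no raw counts used here. Per the submitters' processing notes, the tools used upstream were FastQC, STAR 2.6.1d, featureCounts 1.5.0-p3 and DESeq2 1.26.0, with the genome build hg38. The parameters of these tools, the annotation release and any use of strand are not given in the sources used here. Every one of the 58735 gene identifiers occurs in GENCODE release 29, whose GRCh38 gene positions, symbols and merged exon lengths were used. Without strand, fragments from a gene and from an overlapping gene on the other strand cannot be told apart. Members of families with near-identical copies, such as histone and ribosomal protein genes, carry a further uncertainty from shared reads.

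The table kept the sequencing depth. Multiplying each FPKM by the gene's merged exon length and by 1 factor per library gave whole fragments, within a tolerance of 0.01, for 100% of the values above 0 in each library. The recovered totals lay between 22310806 and 31101932 fragments per library, and between 26548 and 29191 genes had at least 1 fragment. The denominator of each library's FPKM equalled the geometric mean of the totals multiplied by the library's median-of-ratios factor, with a ratio of 1 in all 16 libraries. The deposited FPKM values were thus already scaled by factors of 0.839 to 1.22, and these denominators lay between 0.940 and 1.07 times the library's own total. At this depth counting error was small beside the difference between libraries of 1 group. For the 2 libraries of a group, chi-square per degree of freedom over genes ran from 11.3 in siSETD2 with VE-822 to 138 in untreated siSETD2, so no pair of libraries was a repeat deposit.

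Values were analysed as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (limma-trend, robust estimation off). Fold changes are on this scale, which understates changes of genes near or below 1 FPKM. Genes with a mean of at least 1 FPKM over the 16 libraries were tested, 13088 in all. A model with 1 mean per group was fitted to the 16 libraries, which left 8 residual degrees of freedom, and the variance prior added 2.98. Contrasts were siSETD2 against siNT within each treatment and averaged over the 4 treatments, HU against untreated, VE-822 against untreated, and HU with VE-822 against HU within each siRNA, and the difference of each response between siRNAs. This made 14 planned contrasts. A further pair, HU against untreated and HU with VE-822 against HU, each averaged over both siRNAs, was chosen after the data were seen. Adjusted p-values are Benjamini-Hochberg values over the genes tested in 1 contrast, and 0.05 was the threshold for a call. The samples' groups, the contrasts, the test, the gene lists, the naming rule and a set of other settings were fixed before the data were examined.

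The numbers R1 and R2 paired the libraries in part, as a comparison of their deviations showed. Across genes, the difference R1 minus R2 correlated between groups at 0.363 to 0.746 in all 15 pairs of the 6 groups other than VE-822 alone. In the 12 pairs with 1 VE-822-alone group the correlation was -0.052 to 0.295, and between both VE-822-alone groups it was 0.395. A fit with a replicate block in the 6 groups (a term for the replicate number that is 0 in the 4 VE-822-alone libraries, 7 residual degrees of freedom) was therefore added after this check, beside the planned block over all 8 groups. The pairing comes from the data and the shared numbers, since the labels name no shared culture or day. Fold changes are the same with and without this block, and only their errors differ. "With the block" means this fit with the block in the 6 groups.

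Of 19 gene lists written from general knowledge of the pathways, 18 had at least 3 genes tested. They covered E2F G1/S targets, the E2F, DP and RB family, G2/M genes, p53 targets, dNTP supply, checkpoint and fork protection, enzymes and readers of H3K36 methylation, immediate early genes, NF-kB and cytokine genes, and interferon-stimulated genes. The others were the ATF4 and unfolded protein response, cholesterol synthesis, extracellular matrix and TGF-beta genes, heat shock genes, mitochondrially encoded genes, cytosolic ribosomal proteins, replication-dependent histone genes, and markers of epithelial and of blood cells. Of the markers of other cell types, 4 of 12 epithelial genes and 1 of 14 blood genes were expressed enough to be tested. Histone genes of the replication-dependent class lack poly(A) tails, and only 14 of 71 were tested. Each list was tested against the other genes with limma's camera at a preset correlation between genes of 0.01, adjusted over the 18 lists of a contrast. The same test with an estimated correlation and limma's fry were alternatives. Among all list calls in the 16 contrasts, 1 held with an estimated correlation, that of the ATF4 list between siRNAs in VE-822. A list's members were also counted after adjustment over the list alone. Values within R1 and R2 are given beside many list means of contrasts with no VE-822-alone group, and of the average over the 4 treatments. There the VE-822-alone libraries enter by their numbers, although these do not pair.

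Genes are named by a fixed rule. SETD2 is named wherever the siRNAs are compared. Up to 8 genes that rose and 8 that fell are named by size among called genes with a mean of at least 2 FPKM in the higher group, no overlap between the libraries of both groups (in every treatment for the average over treatments, and not required for a difference of responses) and a gene symbol that is not a clone name or a pseudogene. Of each list, up to 4 called members (8 for E2F G1/S targets) are named by smallest p, and where none is called the member with the highest mean FPKM. E2F1, E2F8, CCNE1, CCNE2, CDC6, RRM2, MCM5, PCNA, CHEK1, WEE1, ATR, CDKN1A, MDM2, GDF15, CCNB1, CDK1, FOS and EGR1 are named wherever tested. Where room is short, the text gives a choice of these genes. Some genes that met the rule are not reported here. The same rule was applied to the calls made with the block. Genes outside the rule are said to have been chosen after their values were seen.

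The calculations were tested on simulated data built from the real means and depths of the 13088 genes, with 67, 67 and 66 genes changed by 1.5, 2 and 4-fold and a replicate difference of the observed size added. For HU against untreated in siNT, these changes were recovered in 8.96%, 58.2% and 89.4% of genes without the block and in 59.7%, 89.6% and 97.0% with it, with 1 and 13 false calls. For siSETD2 averaged over treatments they were 74.6%, 92.5% and 98.5% without and 91.0%, 98.5% and 100% with it, with 0 and 7 false calls. For HU averaged over both siRNAs they were 40.3%, 82.1% and 92.4% without and 74.6%, 97.0% and 98.5% with it, with 3 and 13 false calls. The 18 lists were tested on a separate draw of independent genes with no replicate difference, so power here is unknown. The E2F list, shifted by 0.2 log2, had an adjusted p of 1.41e-19 (0.000109 with an estimated correlation), and 1 unshifted list was called.

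Alternatives fixed in advance were a pseudocount of 0.1, no filter on expression, a filter at a mean of 5 FPKM, rescaling by median ratios, a fit of only the groups compared, a replicate block over all groups, leaving out each library in turn, and the other list tests. Alternatives chosen after the data were seen were the block in the 6 groups, leaving out the VE-822-alone libraries with and without a block, scaling to library totals, and limma-voom on the recovered fragments. Figures and list joins used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. No column of the table was left out.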

Results

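SETD2 siRNA lowered the SETD2 transcript (ENSG00000181555, chr3:47016429-47163967 on the minus strand) in every treatment. Untreated cells held 8.23 ± 0.239 FPKM with siNT and 3.09 ± 1.53 FPKM with siSETD2 (mean ± SD, n = 2), and cells in HU held 8.11 ± 0.0197 and 3.18 ± 1.35 FPKM. In VE-822 the levels were 9.06 ± 0.272 and 4.29 ± 0.474 FPKM, and in HU with VE-822 they were 7.37 ± 0.0509 and 3.15 ± 0.730 FPKM. The transcript that remained was 37.5%, 39.2%, 47.3% and 42.8% of that in siNT. All 8 siSETD2 libraries, at 2.01 to 4.63 FPKM, lay below all 8 siNT libraries, at 7.34 to 9.25 FPKM. Averaged over the treatments the log2 fold change was -1.09 (SE 0.125, adjusted p = 0.0169). Within 1 treatment the fold changes of -1.23, -1.16, -0.93 and -1.02 (SE 0.251) had adjusted p-values of 0.784, 1, 1 and 1, and with the replicate block 0.0846, 0.168, 0.199 and 0.293. The knockdown was deeper in R1 than in R2 libraries without VE-822 alone, at 2.01 against 4.17 FPKM in untreated siSETD2 cells and 2.22 against 4.13 FPKM in HU.

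**Figure D1:**
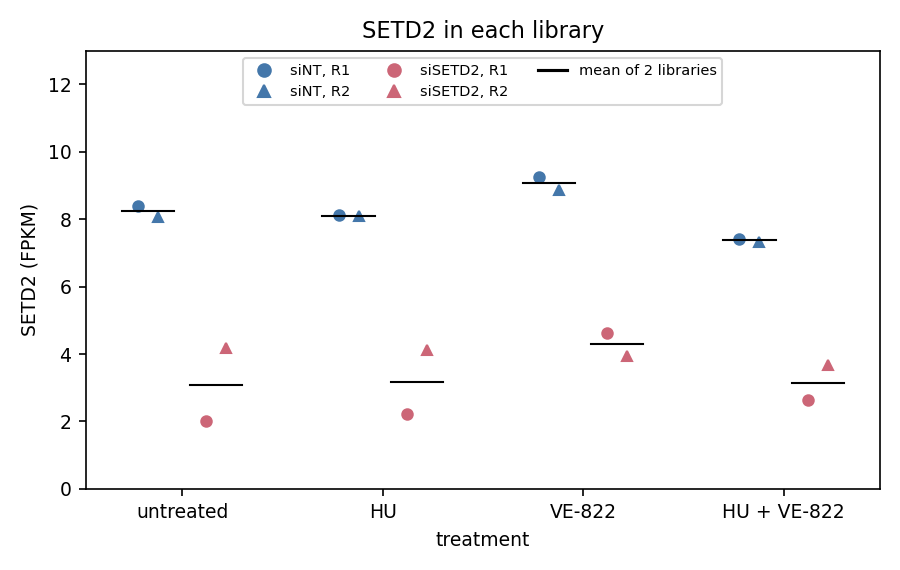
SETD2 transcript (FPKM, vertical axis) in each library by treatment, with siNT in blue, siSETD2 in red, R1 as circles, R2 as triangles and a black line at the mean of 2 libraries. The siSETD2 means were 37.5% to 47.3% of the siNT means.

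Over 13088 genes, the largest difference ran from R1 through R2 to the VE-822-alone libraries. The first principal component held 46.1% of the variance, with VE-822-alone libraries at 29.46 to 35.27, the other R2 libraries at 0.86 to 7.23 and the other R1 libraries at -33.32 to -20.54. The second component held 14.9%. In the 6 groups other than VE-822 alone, R1 and R2 libraries of 1 group lay further apart on both components than siNT and siSETD2 libraries of 1 treatment and replicate number. The difference R1 minus R2 was shared by these groups (correlations across genes of 0.363 to 0.746).

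**Figure D2:**
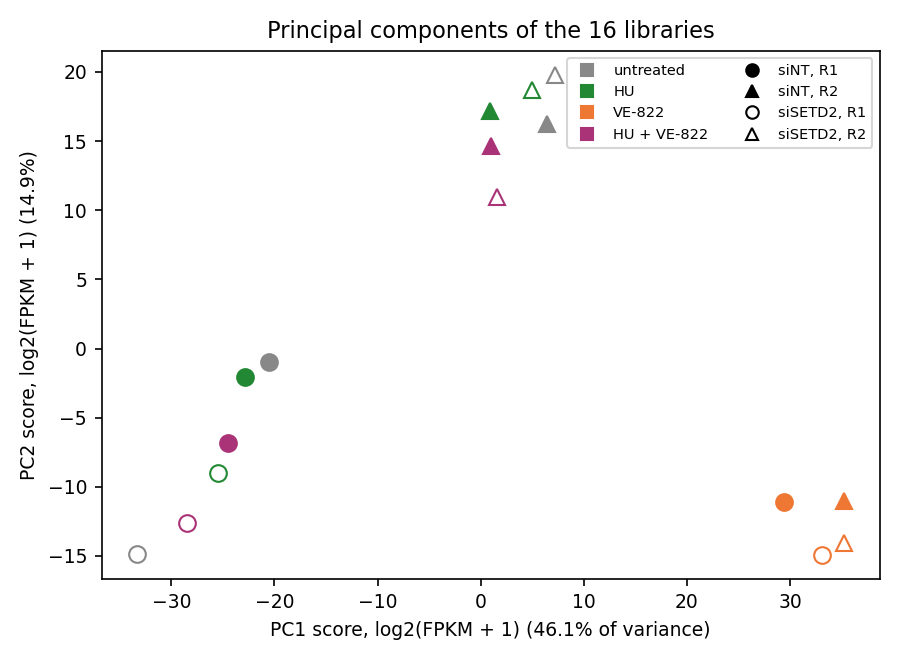
Libraries on the first and second principal components of log2(FPKM + 1), which hold 46.1% and 14.9% of the variance, coloured by treatment, filled for siNT and open for siSETD2, with R1 as circles and R2 as triangles. VE-822-alone libraries lie at 29.46 to 35.27 on the first component, beyond the R2 and R1 libraries of the other treatments.

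Averaged over treatments, siSETD2 raised 4 genes and lowered 13, SETD2 among them, out of 1309 genes with an unadjusted p under 0.05 where chance alone gives 654. This balance turned with the scaling, to 12 up and 5 down scaled to library totals and 3 and 3 after median-ratio rescaling, and 10 of 100 splits of the labels called as many genes. TM9SF3, a membrane protein of the secretory pathway, rose by 0.73 (SE 0.085, adjusted p = 0.0169), and SERBP1, an mRNA-binding protein, rose by 0.64 (SE 0.076, adjusted p = 0.0169). DARS (chr2:135906677-135986100), the cytosolic aspartyl-tRNA synthetase, changed by -1.34 (SE 0.201, adjusted p = 0.0439). COX7A2L, a factor of respiratory supercomplexes, changed by -0.59 (adjusted p = 0.0235), and the G protein subunit GNA12 by -0.57 (adjusted p = 0.0361). DAZAP2, an adaptor protein, changed by -0.46 (adjusted p = 0.0448), and BDH2, a dehydrogenase of iron handling, by -0.40 (adjusted p = 0.0448). The fibronectin-domain protein FNDC3A changed by -0.38 (adjusted p = 0.0439). The number of calls was 0 without any 1 of 10 libraries (untreated siNT R1, both siNT libraries in HU and in VE-822, siNT R1 in HU with VE-822, siSETD2 R1 in HU and in HU with VE-822, and both siSETD2 libraries in VE-822) and 208 without untreated siSETD2 R2. The SETD2 change itself stayed between -1.18 and -0.99 but lost its call without the same number of libraries. DARS was named by rule for the average only. Chosen after its values were seen, its level by treatment was 7.76 ± 3.72 against 22.0 ± 0.104 FPKM untreated, 7.24 ± 4.00 against 24.0 ± 1.13 FPKM in HU. It was 12.2 ± 0.564 against 20.4 ± 3.43 FPKM in VE-822 and 7.94 ± 4.86 against 22.5 ± 2.17 FPKM in HU with VE-822, and no treatment passed the test alone.

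With the replicate block in the 6 groups, chosen after the data were seen, 217 genes rose and 291 fell in siSETD2 averaged over treatments. These 508 calls became 147 with the block over all 8 groups and 47 with a block and no VE-822-alone libraries. Of 100 splits that kept R1 and R2 balanced, only the real one called as many (highest other 6), but 1 without balance called 536. The cystine transporter SLC7A11 (chr4:138164097-138242349) rose by 0.89 (adjusted p = 0.00126), the membrane lipid regulator TLCD1 by 0.69 (adjusted p = 0.00362), and DDIT4, a stress-induced inhibitor of mTORC1, by 0.65 (adjusted p = 0.00983). The Wnt enhancer RSPO3 rose by 0.55 (adjusted p = 0.0211), the sterol sensor INSIG1 by 0.49 (adjusted p = 0.0197). The NF-kB genes BIRC3, TNFAIP3, TRAF1 and NFKB2 rose by 0.53, 0.45, 0.44 and 0.33 (adjusted p = 0.0163, 0.043, 0.0462 and 0.0449). RRM2, the small subunit of ribonucleotide reductase, rose by 0.31 (adjusted p = 0.049), while its p53-induced relative RRM2B changed by -0.32 (adjusted p = 0.024). XRCC5, a subunit of the Ku end-joining complex, changed by -0.86 (adjusted p = 0.00621), and the chromatin protein HMGA2 by -0.56 (adjusted p = 0.00126). The matrix genes FN1, COL6A3 (chr2:237324003-237414375), COL5A2 and SPARC changed by -0.54, -0.51, -0.41 and -0.38 (adjusted p = 0.0124, 0.00751, 0.00763 and 0.014). The semaphorin SEMA7A changed by -0.67 (adjusted p = 0.0034), the mitochondrial protease YME1L1 by -0.58 (adjusted p = 0.00994), and MT-ND5, MT-ND6 and MT-ND1 by -0.45, -0.41 and -0.32 (adjusted p = 0.0156, 0.0295 and 0.0485). DNMT3A, a DNA methyltransferase that reads H3K36 methylation, changed by -0.25 (adjusted p = 0.0143). Of E2F targets and related genes, MCM4 changed by -0.23 (adjusted p = 0.0351), FANCD2 by -0.20 (adjusted p = 0.0457) and the activator E2F3 by 0.20 (adjusted p = 0.0373). CCNE1, CCNE2, CDC6, PCNA, MCM5, E2F1, CHEK1, WEE1, CDKN1A and ATR differed by 0.076, 0.043, -0.092, 0.001, -0.098, 0.18, -0.056, -0.14, 0.13 and -0.006, and none passed.

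As groups averaged over treatments, all 13 mitochondrially encoded genes were lower in siSETD2 (mean log2 fold change -0.27, adjusted p = 1.17e-05, 0.463 with an estimated correlation), with 2 fallen when adjusted over the list alone. NF-kB and cytokine genes were higher in 17 of 20 (mean 0.22, adjusted p = 3.57e-06, 0.337 with an estimated correlation), with 4 risen when adjusted over the list alone. ATF4 and unfolded protein response genes were higher in 19 of 25 (mean 0.16, adjusted p = 0.000799, 0.141 with an estimated correlation). Cholesterol synthesis genes were higher in 19 of 23 (mean 0.10, adjusted p = 0.0012, 0.141 with an estimated correlation). Enzymes and readers of H3K36 methylation were lower in 19 of 25 (mean -0.10, adjusted p = 0.00439, 0.141 with an estimated correlation), a list that holds SETD2 itself, and 2 fell when adjusted over the list alone. The E2F, DP and RB family was lower in 17 of 24 (mean -0.055, adjusted p = 0.0401, 0.141 with an estimated correlation; 0.0519 with the block). Immediate early genes were higher in 16 of 24 (mean 0.060, adjusted p = 0.0431, 0.64 with an estimated correlation; 0.0519 with the block). Cytosolic ribosomal protein genes had a mean of 0.068 (40 of 45 higher, adjusted p = 0.00439, 0.886 with an estimated correlation). The mean was 0.19 within R1 and -0.050 within R2, so this relation did not hold within both. Further means within R1 and R2 (VE-822-alone libraries by number, unpaired) were -0.30 and -0.23 (mitochondrial) and 0.26 and 0.18 (NF-kB). They were 0.20 and 0.11 (ATF4), 0.14 and 0.068 (cholesterol) and -0.12 and -0.091 (H3K36).

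E2F G1/S targets were lower in 44 of 68 in siSETD2 averaged over treatments (mean -0.058, adjusted p = 0.0721), at -0.082 within R1 and -0.033 within R2, and passed only with the block (adjusted p = 0.00805, 0.577 with an estimated correlation). Extracellular matrix and TGF-beta genes were lower in 20 of 28 (mean -0.11, adjusted p = 0.229) and also passed only with the block (adjusted p = 0.0145, 0.53 with an estimated correlation), with 1 member risen and 5 fallen. The 4 epithelial markers expressed were all higher (mean 0.14, adjusted p = 0.148, 0.02 with the block), among them the claudin CLDN4 at 0.28 (adjusted p = 0.0127 with the block). G2/M genes (mean -0.011, adjusted p = 0.876), p53 targets (-0.042, 0.274), dNTP supply (-0.029, 0.876), checkpoint and fork protection (-0.037, 0.274), interferon-stimulated genes (-0.015, 0.523), heat shock genes (-0.0066, 0.876) and replication-dependent histone genes (0.076, 0.229) did not pass. The only blood cell marker expressed, CD3D, differed by -0.19 and formed no list.

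Without drug, siSETD2 lowered extracellular matrix and TGF-beta genes as a group, with all 28 lower (mean -0.35, adjusted p = 8.02e-05, 0.624 with an estimated correlation) and a mean of -0.48 within R1 and -0.21 within R2. With the block, 12 of them fell when adjusted over the list alone. Enzymes and readers of H3K36 methylation were lower in 21 of 25 (mean -0.16, adjusted p = 0.00269, 0.288 with an estimated correlation; -0.20 within R1, -0.12 within R2), with 2 fallen when adjusted over the list alone. Mitochondrially encoded genes were lower in 12 of 13 (mean -0.28, adjusted p = 0.00968, 0.624 with an estimated correlation; -0.29 within R1, -0.27 within R2). NF-kB genes were higher in 16 of 20 (mean 0.15, adjusted p = 0.0334, 0.624 with an estimated correlation; 0.29 within R1, 0.017 within R2). Ribosomal protein genes were higher in 44 of 45 (mean 0.23, adjusted p = 2.38e-09, 0.624 with an estimated correlation), but not within R2, where the mean was -0.061 against 0.52 within R1. The E2F G1/S targets did not differ as a group (mean -0.037, adjusted p = 0.661; -0.016 within R1, -0.059 within R2), although the mean ran from -0.17 without siNT R1 (adjusted p = 0.00516) to 0.096 without siNT R2 (adjusted p = 0.0262). Of single genes, limma called 0, with 578 at an unadjusted p under 0.05 where chance gives 654, and voom called 0. The block gave 1, the cell-surface hyaluronidase CEMIP2 (-0.86, adjusted p = 0.0296 with the block, 4.93 ± 0.855 FPKM in siSETD2). Without untreated siSETD2 R2, 160 genes were called.

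In HU, E2F G1/S targets were lower in siSETD2 than in siNT in 55 of 68 genes (mean -0.12, adjusted p = 0.0085, 0.926 with an estimated correlation). The mean was -0.16 within R1 and -0.076 within R2, and adjusted p was 0.000105 with the block and 0.585 with the block and an estimated correlation. No member passed when adjusted over the list alone. CDC6, which loads the MCM helicase, stood at 20.5 ± 1.74 FPKM against 23.2 ± 1.39 FPKM in siNT (-0.17) and the replication clamp PCNA at 118.4 ± 24.4 against 130.2 ± 15.0 FPKM (-0.15). The checkpoint kinase CHEK1 differed by -0.22, and cyclin E1 (CCNE1) stood at 26.1 ± 3.21 against 27.3 ± 3.29 FPKM. In the other direction RRM2 differed by 0.11 and E2F1 by 0.072 (26.5 ± 16.3 against 23.5 ± 8.45 FPKM). The list mean went to 0.064 without siSETD2 R1 in HU (adjusted p = 0.458) and 0.020 without siNT R2 in HU (adjusted p = 0.689), each of which leaves unequal numbers of R1 and R2 libraries. The E2F, DP and RB family was lower in 17 of 24 (mean -0.099, adjusted p = 0.042, 0.184 with an estimated correlation; -0.15 within R1, -0.049 within R2). NF-kB genes were higher in 15 of 20 (mean 0.13, adjusted p = 0.0085, 0.823 with an estimated correlation; 0.091 within R1, 0.17 within R2). Cholesterol synthesis genes were higher in 20 of 23 (mean 0.15, adjusted p = 0.000116, 0.167 with an estimated correlation; 0.21 within R1, 0.088 within R2). Single genes called by limma numbered 0, with 337 at an unadjusted p under 0.05, and 0 by voom.

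In VE-822 alone, all 25 ATF4 and unfolded protein response genes were higher in siSETD2 than in siNT (mean 0.30, adjusted p = 6.95e-09, 0.0491 with an estimated correlation; 0.268 with the block and an estimated correlation). NF-kB genes were higher in 19 of 20 (mean 0.38, adjusted p = 8.98e-09, 0.335 with an estimated correlation). Interferon-stimulated genes were higher in 22 of 32 (mean 0.18, adjusted p = 0.00643, 0.676 with an estimated correlation). Immediate early genes were higher in 18 of 24 (mean 0.11, adjusted p = 0.0366, 0.676 with an estimated correlation). Extracellular matrix genes were higher in 17 of 28 (mean 0.11, adjusted p = 0.0335, 0.676 with an estimated correlation). Heat shock genes were lower in 12 of 13 (mean -0.16, adjusted p = 0.0259, 0.676 with an estimated correlation). Mitochondrially encoded genes were lower in 11 of 13 (mean -0.18, adjusted p = 0.0195, 0.699 with an estimated correlation). H3K36 enzymes and readers were lower in 20 of 25 (mean -0.10, adjusted p = 0.0195, 0.335 with an estimated correlation). E2F G1/S targets were lower in 53 of 68 (mean -0.068, adjusted p = 0.0869, 0.0134 with the block and 0.554 with the block and an estimated correlation). With the block 6 genes rose, among them the secreted cystatin CST1 by 1.14 (adjusted p = 0.0066) and the transporter ABCC2 by 0.86 (adjusted p = 0.0106). Also risen were the protease MMP10 at 1.39 (adjusted p = 0.0222), the kinase IRAK2 at 0.90 (adjusted p = 0.0311) and SLC7A11 at 1.30 (adjusted p = 0.0222), at 18.9 ± 2.15 against 7.05 ± 0.382 FPKM. Without it limma called 0 genes, with 384 at an unadjusted p under 0.05, and voom called 0.

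In HU with VE-822, all 13 mitochondrially encoded genes were lower in siSETD2 (mean -0.45, adjusted p = 1.64e-10, 0.344 with an estimated correlation; -0.53 within R1, -0.37 within R2). G2/M genes were higher in 40 of 47 (mean 0.12, adjusted p = 0.000346, 0.814 with an estimated correlation; 0.19 within R1, 0.046 within R2). ATF4 genes were higher in 19 of 25 (mean 0.23, adjusted p = 0.000168, 0.174 with an estimated correlation; 0.32 within R1, 0.14 within R2). NF-kB genes were higher in 17 of 20 (mean 0.22, adjusted p = 0.000869, 0.665 with an estimated correlation; 0.26 within R1, 0.17 within R2). Cholesterol synthesis genes were higher in 20 of 23 (mean 0.17, adjusted p = 0.000331, 0.174 with an estimated correlation; 0.24 within R1, 0.10 within R2). Interferon-stimulated genes were lower in 25 of 32 (mean -0.14, adjusted p = 0.000869, 0.665 with an estimated correlation; -0.26 within R1, -0.028 within R2). Ribosomal protein genes were higher in 40 of 45 (mean 0.11, adjusted p = 0.00866, 0.814 with an estimated correlation; 0.0501 with the block), but at 0.27 within R1 and -0.059 within R2. No difference was seen in E2F G1/S targets (mean -0.0047, adjusted p = 0.853; -0.031 within R1, 0.022 within R2). Limma and voom each called 0 genes, with 285 at an unadjusted p under 0.05 in limma.

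Averaged over both siRNAs, HU for 4 h changed single genes of mitosis and stress. The centromeric histone CENPA (chr2:26764289-26801067) changed by -0.85 (SE 0.096, adjusted p = 0.0155) and the spindle protein PSRC1 (chr1:109279556-109283186) by -1.48 (SE 0.194, adjusted p = 0.0225). The G2-phase helicase PIF1 changed by -1.45 (SE 0.214, adjusted p = 0.0313) and the mitochondrial carrier SLC25A27 by -0.59 (SE 0.08, adjusted p = 0.0303). RSPO3 rose by 1.45 (SE 0.211, adjusted p = 0.0313) and the stress-induced transcription factor ATF3 (chr1:212565334-212620777) by 0.83 (SE 0.123, adjusted p = 0.0313). The p53-induced phosphatase PPM1D (chr17:60600183-60666280) rose by 0.70 (SE 0.101, adjusted p = 0.0313), the calcium-release inhibitor ITPRIP by 0.69 (SE 0.098, adjusted p = 0.0313) and the adhesion protein AMIGO2 by 0.51 (adjusted p = 0.0425). In siNT, CENPA went from 12.4 ± 1.79 to 6.28 ± 0.220 FPKM and PSRC1 from 20.5 ± 9.37 to 6.29 ± 0.737 FPKM. In siSETD2, CENPA went from 12.99 ± 0.758 to 6.87 ± 0.540 FPKM and PSRC1 from 21.5 ± 6.99 to 6.95 ± 1.05 FPKM. This average called 5 genes up and 9 down, with 992 at an unadjusted p under 0.05, and 2 of 35 splits of the 8 libraries called as many genes as the real one. None was called without untreated siNT R2 or any 1 of the 4 HU libraries, and 52 were called without untreated siSETD2 R1.

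With the replicate block, 111 genes rose and 98 fell in HU averaged over both siRNAs. Cyclin E2 (CCNE2, chr8:94879770-94896678), an E2F target that drives entry into S phase, rose by 0.73 (adjusted p = 0.00272). It went from 1.11 ± 0.502 to 2.57 ± 0.698 FPKM in siNT and from 1.24 ± 0.395 to 2.68 ± 1.20 FPKM in siSETD2. Further E2F targets that rose were the phosphatase CDC25A (0.41, adjusted p = 0.0471), the origin protein ORC1 (0.39, adjusted p = 0.0493) and the repressor E2F7 (0.37, adjusted p = 0.036). The fork protein TIMELESS, of the checkpoint list, rose by 0.29 (adjusted p = 0.0367). Of p53 targets, PLK2 rose by 0.94 (adjusted p = 0.0378), BTG2 by 0.87 (adjusted p = 0.0287) and SESN2 by 0.55 (adjusted p = 0.019). TP53INP1 rose by 0.42 (adjusted p = 0.0266) and the repair gene XPC by 0.40 (adjusted p = 0.0177). Cytokine and NF-kB genes rose, with CXCL8 at 1.42 (adjusted p = 0.0496), CCL2 at 1.03 (adjusted p = 0.0202) and TNFAIP3 at 0.97 (adjusted p = 0.012). INHBA stood at 0.90 (adjusted p = 0.017), IL11 at 0.86 (adjusted p = 0.0202) and IL6 (chr7:22725884-22732002) at 0.77 (adjusted p = 0.00272). The immediate early genes NR4A2 and DUSP1 rose by 0.84 and 0.71 (adjusted p = 0.002 and 0.00941). The linker histone H1F0 (chr22:37805093-37807436) changed by -1.12 (adjusted p = 0.00184) and the mitotic ubiquitin-conjugating enzyme UBE2C by -0.69 (adjusted p = 0.0076). The kinase AURKA changed by -0.63 (adjusted p = 0.0134), the chromosome protein CDCA2 by -0.70 (adjusted p = 0.0304) and the inhibitor CDKN2D by -0.45 (adjusted p = 0.0304). CDKN1A (chr6:36676460-36687339), the p53-induced inhibitor of cyclin-dependent kinases, differed by 0.84 without passing (adjusted p = 0.0607 with the block). Its levels were 127.2 ± 24.2 against 67.9 ± 28.5 FPKM in siNT and 134.3 ± 4.77 against 88.1 ± 50.8 FPKM in siSETD2. GDF15, MDM2, PCNA, E2F1, CDC6, RRM2 and CCNE1 differed by 0.78, 0.50, 0.43, 0.40, 0.33, 0.31 and 0.29, and CCNB1, WEE1 and CDK1 by -0.36, -0.39 and -0.16, none past the test.

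Within siNT, the 47 G2/M genes fell as a group in HU, with 46 lower (mean -0.45, adjusted p = 6.57e-37, 0.174 with an estimated correlation; -0.35 within R1, -0.56 within R2) and 14 fallen when adjusted over the list alone. All 32 p53 targets were higher (mean 0.44, adjusted p = 4.19e-17, 0.174 with an estimated correlation; 0.29 within R1, 0.59 within R2). So were 61 of 68 E2F G1/S targets (mean 0.21, adjusted p = 1.58e-07, 0.621 with an estimated correlation; 0.20 within R1, 0.22 within R2). NF-kB genes were higher in 19 of 20 (mean 0.54, adjusted p = 1.44e-10, 0.182 with an estimated correlation; 0.39 within R1, 0.68 within R2). Immediate early genes were higher in 20 of 24 (mean 0.27, adjusted p = 3.6e-05, 0.225 with an estimated correlation; 0.14 within R1, 0.40 within R2). ATF4 genes were higher in 21 of 25 (mean 0.20, adjusted p = 0.000294, 0.174 with an estimated correlation; 0.11 within R1, 0.29 within R2). dNTP supply genes were higher in 18 of 21 (mean 0.17, adjusted p = 0.00477, 0.233 with an estimated correlation; 0.15 within R1, 0.19 within R2). Ribosomal protein genes were higher in 44 of 45 (mean 0.12, adjusted p = 0.00722, 0.682 with an estimated correlation; 0.10 within R1, 0.13 within R2). All 14 histone genes tested were lower (mean -0.23, adjusted p = 0.02, 0.682 with an estimated correlation; -0.19 within R1, -0.26 within R2). So were all 13 mitochondrially encoded genes (mean -0.15, adjusted p = 0.0295, 0.682 with an estimated correlation; -0.23 within R1, -0.076 within R2). Lower as well were 18 of 23 cholesterol synthesis genes (mean -0.090, adjusted p = 0.02, 0.233 with an estimated correlation; -0.097 within R1, -0.082 within R2). Heat shock genes (mean 0.14, adjusted p = 0.0628; 0.0466 with the block, 0.567 with the block and an estimated correlation) passed only with the block. The E2F, DP and RB family (mean 0.047, adjusted p = 0.539), checkpoint and fork protection genes (0.050, 0.471), H3K36 enzymes and readers (-0.011, 0.568), interferon-stimulated genes (-0.023, 0.511), matrix genes (0.044, 0.866) and epithelial markers (0.18, 0.539) did not pass.

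Single genes within siNT passed with the block only, where 7 rose and 15 fell in HU. RSPO3 rose by 1.54 (adjusted p = 0.0306), IL6 by 0.98 (adjusted p = 0.0253), to 3.03 ± 1.95 from 1.03 ± 0.938 FPKM, and NR4A2 by 0.95 (adjusted p = 0.0306). PPM1D rose by 0.77 (adjusted p = 0.0469), to 16.5 ± 1.004 from 9.29 ± 0.811 FPKM, CCNE2 by 0.77 (adjusted p = 0.0429) and the receptor TNFRSF9 by 0.73 (adjusted p = 0.0469). PSRC1, H1F0, CENPA and the dehydrogenase DHRS2 changed by -1.49, -1.06, -0.88 and -0.69 (adjusted p = 0.0326, 0.0337, 0.0328 and 0.0328). CDC6 stood at 23.2 ± 1.39 against 17.6 ± 2.04 FPKM and PCNA at 130.2 ± 15.0 against 85.8 ± 6.23 FPKM. CCNE1 stood at 27.3 ± 3.29 against 20.9 ± 4.86 FPKM and the p53 target GDF15 at 69.2 ± 4.30 against 39.5 ± 16.1 FPKM, and none of these passed. Without the block limma called 0, with 427 at an unadjusted p under 0.05, and voom called 0. The E2F mean in siNT was 0.069 without siNT R2 in HU (adjusted p = 0.127) and 0.076 without untreated siNT R1 (adjusted p = 0.256).

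Within siSETD2, HU lowered 46 of 47 G2/M genes as a group (mean -0.42, adjusted p = 1.85e-29, 0.27 with an estimated correlation; -0.27 within R1, -0.57 within R2), with 16 fallen when adjusted over the list alone. p53 targets were higher in 30 of 32 (mean 0.40, adjusted p = 1.08e-15, 0.27 with an estimated correlation; 0.11 within R1, 0.70 within R2), with 9 risen when adjusted over the list alone. All 20 NF-kB genes were higher (mean 0.52, adjusted p = 1.29e-09, 0.292 with an estimated correlation; 0.19 within R1, 0.84 within R2). So were 27 of 28 matrix genes (mean 0.30, adjusted p = 6.36e-05, 0.403 with an estimated correlation; 0.31 within R1, 0.28 within R2). E2F G1/S targets were higher in 52 of 68 (mean 0.13, adjusted p = 0.00842, 0.711 with an estimated correlation; 0.054 within R1, 0.20 within R2). Immediate early genes were higher in 20 of 24 (mean 0.22, adjusted p = 0.000793, 0.403 with an estimated correlation), though at 0.0052 within R1 and 0.43 within R2. Ribosomal protein genes were lower in all 45 (mean -0.19, adjusted p = 2.39e-06, 0.711 with an estimated correlation), but only within R1 (-0.54 against 0.16 within R2). dNTP supply genes did not pass (mean -0.0039, adjusted p = 0.784; -0.16 within R1, 0.15 within R2). Histone genes passed only with the block (mean -0.31, adjusted p = 3.06e-05, 0.193 with the block and an estimated correlation; -0.44 within R1, -0.17 within R2). ATF4 genes had a mean of 0.11 (adjusted p = 0.0795, 0.0453 with the block, 0.619 with the block and an estimated correlation). It was -0.014 within R1 and 0.24 within R2.

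With the block, 10 genes rose and 16 fell in HU in siSETD2, with RSPO3 (1.35, adjusted p = 0.0373), TNFRSF9 (0.91, adjusted p = 0.0261) and the muscle protein ADPRHL1 (0.87, adjusted p = 0.0375) among the risen. Others that rose were ITPRIP (0.85, adjusted p = 0.0332), the zinc-finger protein ZBTB38 (0.65, adjusted p = 0.0349) and the p53 target SUSD6 (0.64, adjusted p = 0.0332). PSRC1, H1F0, CENPA, the ribonuclease RNASE1 and SLC25A27 changed by -1.47, -1.18, -0.83, -0.75 and -0.74 (adjusted p = 0.0332, 0.0261, 0.0332, 0.0332 and 0.0264). CCNE2 differed by 0.69 (adjusted p = 0.0564 with the block), beside 0.77 in siNT, and the difference of -0.079 between siRNAs did not pass. Without the block limma and voom called 0, with 578 at an unadjusted p under 0.05 in limma, and 50 genes were called without untreated siSETD2 R2. Without siSETD2 R2 in HU the E2F mean was -0.058 (adjusted p = 0.473), and without untreated siSETD2 R1 it was 0.014 (adjusted p = 0.858).

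The HU responses of siNT and siSETD2 cells, which share no library, correlated at 0.429 over 13088 genes with 62.0% of the same sign. Over the 500 genes with the smallest p in siNT the correlation was 0.785, with 451 of the same sign, and over the 22 genes called with the block in siNT it was 0.955, with 21 of the same sign. With the block, 3 risen and 9 fallen genes were called in both siRNAs where chance gives 0. Averaged over both siRNAs, G2/M genes were lower in 46 of 47 (mean -0.44, adjusted p = 1.25e-40, 0.153 with an estimated correlation), with 2 fallen, 31 when adjusted over the list alone and 40 so adjusted with the block. All 32 p53 targets were higher (mean 0.42, adjusted p = 3.38e-20, 0.153 with an estimated correlation), 16 of them risen when adjusted over the list alone. All 20 NF-kB genes were higher too (mean 0.53, adjusted p = 1.69e-12, 0.17 with an estimated correlation), 6 risen so adjusted. E2F G1/S targets were higher in 62 of 68 (mean 0.17, adjusted p = 3.77e-06, 0.635 with an estimated correlation), with 4 risen with the block, and without siSETD2 R2 in HU the mean was 0.076 (adjusted p = 0.0537). Immediate early genes were higher in 21 of 24 (mean 0.24, adjusted p = 1.9e-05, 0.203 with an estimated correlation) and ATF4 genes in 18 of 25 (mean 0.15, adjusted p = 0.00186, 0.203 with an estimated correlation). Higher as well were 25 of 28 matrix genes (mean 0.17, adjusted p = 0.0148, 0.635 with an estimated correlation). Histone genes were lower in 13 of 14 (mean -0.27, adjusted p = 0.0176, 0.635 with an estimated correlation).

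**Figure D3:**
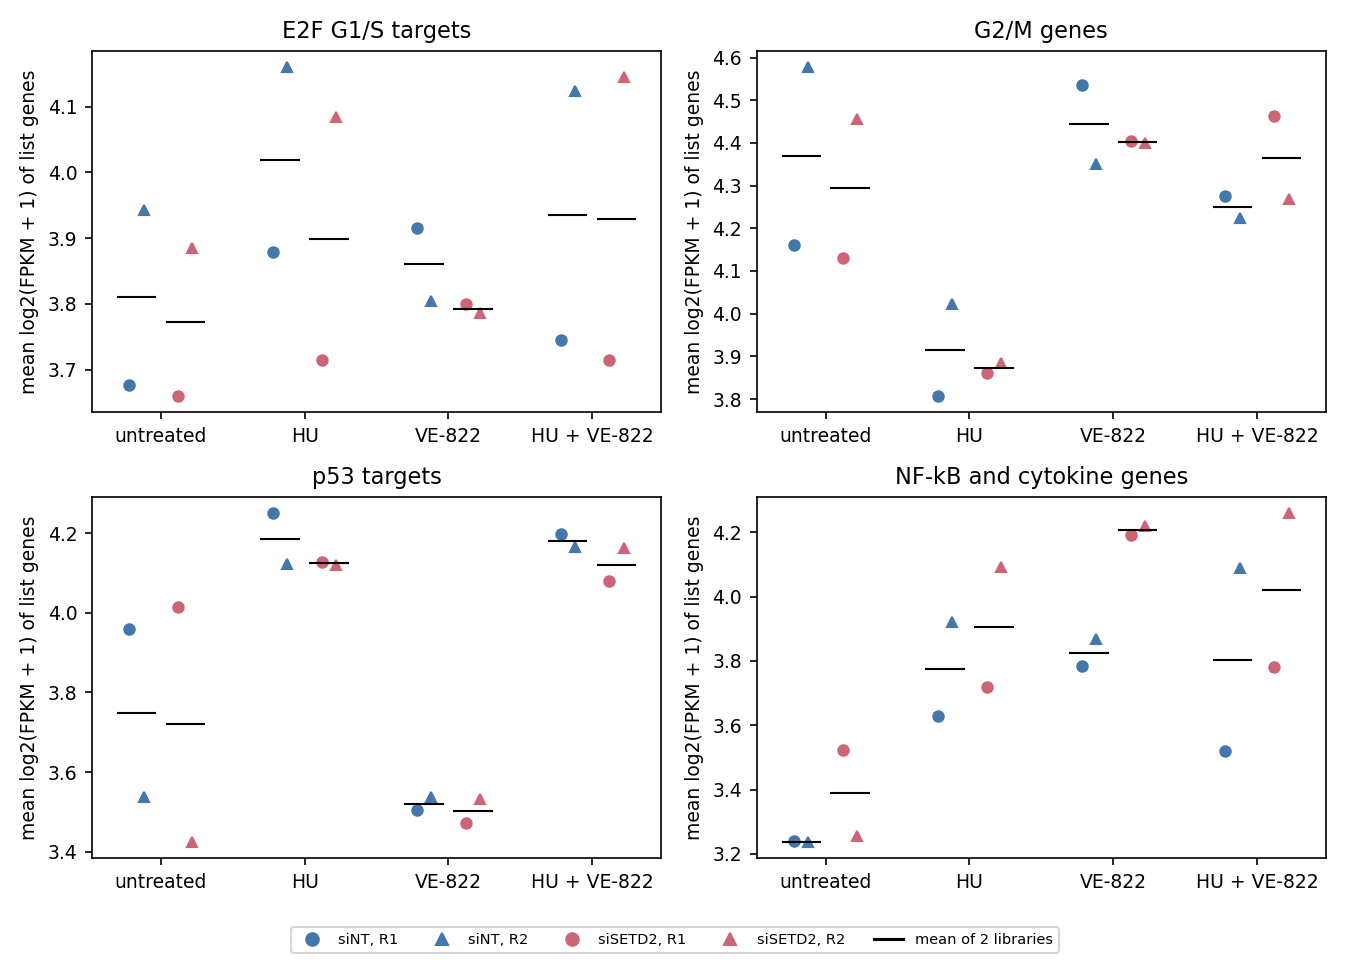
Mean log2(FPKM + 1) of E2F G1/S targets (68 genes), G2/M genes (47), p53 targets (32) and NF-kB genes (20) in each library by treatment, with siNT in blue, siSETD2 in red, R1 as circles and R2 as triangles. G2/M genes were lower in HU (mean log2 fold changes -0.45 in siNT and -0.42 in siSETD2) and higher again with VE-822 added (0.33 and 0.49).

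The response to HU differed between siRNAs in 5 lists and in 0 single genes by limma (97 at an unadjusted p under 0.05, 0 by voom). Matrix genes responded more in siSETD2, in 27 of 28 (mean difference 0.25, adjusted p = 0.000243, 0.735 with an estimated correlation; 0.34 within R1, 0.16 within R2), from their lower untreated level. dNTP supply genes responded less, in 19 of 21 (mean difference -0.17, adjusted p = 0.00885, 0.735 with an estimated correlation; -0.31 within R1, -0.040 within R2), with RRM2 at -0.30. Heat shock genes responded less in 12 of 13 (-0.21, adjusted p = 0.0319, 0.735 with an estimated correlation; -0.33 within R1, -0.086 within R2). Interferon-stimulated genes responded more in 25 of 32 (0.12, adjusted p = 0.0332, 0.741 with an estimated correlation; 0.030 within R1, 0.21 within R2). Ribosomal protein genes responded less in all 45 (-0.30, adjusted p = 9.7e-13, 0.735 with an estimated correlation), but only within R1 (-0.64 against 0.035 within R2). For E2F G1/S targets the mean difference was -0.083 with 51 of 68 lower (adjusted p = 0.0616; -0.15 within R1, -0.017 within R2), and with the block it passed (adjusted p = 0.0126, 0.665 with an estimated correlation). PCNA differed by -0.32 and CCNE2 by -0.079, neither past the test.

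VE-822 alone had more genes called against untreated cells than HU alone, among them PCDH7, CCL5 and MARCH4. These 4 libraries stood apart from all others. Over the 549 genes called in both siRNAs the change followed R2 minus R1 in HU (correlation 0.576, same sign in 69.2%), so a batch is not excluded. PCDH7 (chr4:30720415-31146805), a protocadherin, rose from 1.51 ± 0.944 to 32.1 ± 6.67 FPKM in siNT (log2 fold change 3.76, adjusted p = 0.0248). In siSETD2 it rose from 1.21 ± 0.976 to 31.3 ± 0.315 FPKM (3.94, adjusted p = 0.0147). CCL5 (chr17:35871491-35880793), a T-cell chemokine, rose from 5.56 ± 0.973 to 18.2 ± 0.138 FPKM in siNT (1.56, adjusted p = 0.00404). Its rise in siSETD2 was from 4.05 ± 1.95 to 39.7 ± 2.54 FPKM (3.07, adjusted p = 0.000184). MARCH4 (chr2:216257865-216372027), a membrane ubiquitin ligase, fell from 24.0 ± 7.73 to 3.86 ± 0.950 FPKM in siNT (-2.34, adjusted p = 0.00043) and changed by -2.26 in siSETD2 (adjusted p = 0.000284). In siNT 307 genes rose and 377 fell, 135 and 90 of them by at least 2-fold. In siSETD2 758 rose and 675 fell, 218 and 103 by at least 2-fold. Of these, 271 rose and 278 fell in both siRNAs (17.8 and 19.4 by chance). The responses correlated at 0.834 over all genes and 0.963 over the 684 called in siNT, 680 of the same sign. A batch in VE-822-alone libraries could give both.

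Other genes that rose in VE-822 alone, in siNT and siSETD2 in turn, were the growth factor BMP4 (2.72 and 2.63, adjusted p = 0.00233 and 0.00217) and the secreted lectin CHI3L1 (2.71 and 2.57, adjusted p = 0.0166 and 0.0151). The neurotrophin receptor NGFR (2.599 and 2.85, adjusted p = 0.000727 and 0.000284) and the serotonin-gated channel HTR3A (2.56 and 2.81, adjusted p = 0.000859 and 0.000361) rose likewise. In siNT the transcription factor MAF rose to 11.3 ± 1.74 from 0.933 ± 0.325 FPKM (2.67, adjusted p = 0.000416) and IGFBP5, which binds insulin-like growth factors, by 2.73 (adjusted p = 0.0422). FRMD6, an activator of the Hippo pathway, changed by -2.18 and -2.04 (adjusted p = 0.00819 and 0.00866), and TUFT1 by -1.59 and -1.73 (adjusted p = 0.000416 and 0.000184). CD274 (chr9:5450503-5470566), which encodes the immune checkpoint ligand PD-L1, fell to 2.00 ± 0.288 from 8.63 ± 1.51 FPKM in siNT (-1.68, adjusted p = 0.00474) and changed by -1.64 in siSETD2 (adjusted p = 0.00397). The actin crosslinker FLNC fell in siNT to 70.8 ± 2.68 from 250.9 ± 99.1 FPKM (-1.75, adjusted p = 0.00232). The phosphatase DUSP5 and the AP-1 subunit FOSL1, both targets of ERK signalling, changed by -1.33 and -1.08 in siNT (adjusted p = 0.00206 and 0.023) and by -1.38 and -1.10 in siSETD2 (adjusted p = 0.00127 and 0.0151).

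Interferon-stimulated genes were higher in VE-822 alone in 29 of 32 in siNT (mean 0.63, adjusted p = 1.43e-09, 0.812 with an estimated correlation). In siSETD2 30 of 32 were higher (mean 0.92, adjusted p = 3.66e-12, 0.502 with an estimated correlation). Of them 8 and 14 rose, and 11 and 20 when adjusted over the list alone. Of markers of other cell types, the epithelial list did not pass, with means of 0.50 and 0.50 (adjusted p = 0.56 and 0.462, 2 of 4 higher in each siRNA), and the blood marker CD3D differed by 0.42 in siNT (adjusted p = 0.211) and rose by 0.78 in siSETD2 (adjusted p = 0.0204). In HU the interferon list was lower in R2 than in R1 (2.26 against 2.62 mean log2 in siNT, 2.27 against 2.62 in siSETD2), opposite to its rise in VE-822 alone. CXCL10 rose by 1.29 and 2.31 (adjusted p = 0.00743 and 0.000284), the RNA sensor-like OASL by 1.35 and 1.39 (adjusted p = 0.000824 and 0.000448), and in siNT the tetherin gene BST2 by 1.62 (adjusted p = 0.00303). NF-kB genes were higher in 14 of 20 in siNT (mean 0.59, adjusted p = 0.00201, 0.928 with an estimated correlation), with 2 risen. In siSETD2 18 of 20 were higher (mean 0.82, adjusted p = 8.56e-05, 0.797 with an estimated correlation), with 6 risen. BIRC3 rose by 1.62 and 2.08 (adjusted p = 0.0111 and 0.00251) and SOD2 by 1.65 and 1.79 (adjusted p = 0.00104 and 0.000481). In siSETD2 CCL2 rose to 33.0 ± 1.93 from 5.49 ± 0.683 FPKM (2.39, adjusted p = 0.0226; 1.87 in siNT, adjusted p = 0.0824; difference between siRNAs 0.52, adjusted p = 1). Matrix genes passed in siSETD2 (23 of 28 higher, mean 0.54, adjusted p = 0.0011, 0.797 with an estimated correlation), with 8 risen, and not in siNT (mean 0.084, adjusted p = 0.56). COL6A3 rose in siSETD2 to 13.4 ± 0.0946 from 3.54 ± 0.947 FPKM (1.68, adjusted p = 0.0107) and COL6A1 by 1.18 (adjusted p = 0.00608). COL5A1 rose by 1.74 and 2.11 in siNT and siSETD2 (adjusted p = 0.0439 and 0.0144).

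Cell-cycle lists did not pass in VE-822 alone. The E2F G1/S list had means of 0.050 and 0.020 in siNT and siSETD2 (adjusted p = 0.569 and 0.978), G2/M genes 0.074 and 0.11 (adjusted p = 0.451 and 0.325) and p53 targets -0.23 and -0.22 (adjusted p = 0.0927 and 0.2). Of single genes CDC25A changed by -0.52 (adjusted p = 0.0305) and BRCA2 by 0.42 (adjusted p = 0.0484) in siSETD2, as did CCND1 by -0.77 (adjusted p = 0.0254) and RBL2 by 0.53 (adjusted p = 0.0401). FAS rose there by 0.84 (adjusted p = 0.0464), and CD3D stood at 2.75 ± 0.177 against 1.19 ± 0.176 FPKM. CDKN1A differed by -0.93 and -1.11, E2F1 by 0.64 and 0.63, CCNE1 by -0.57 and -0.55, CHEK1 by 0.52 and 0.51 and PCNA by 0.20 and 0.015, none past the test. In siNT, dNTP supply (mean -0.15, adjusted p = 0.455), the ATF4 list (-0.075, 0.56), cholesterol synthesis (0.12, 0.217), heat shock (0.020, 0.811), mitochondrially encoded (0.092, 0.56), ribosomal protein (0.063, 0.455) and histone genes (-0.18, 0.751) did not pass. The number of genes called ran from 132 without untreated siNT R1 to 992 without an untreated siSETD2 library in siNT, and in siSETD2 from 219 without siSETD2 R1 in VE-822 to 3325 without untreated siSETD2 R2.

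**Figure D4:**
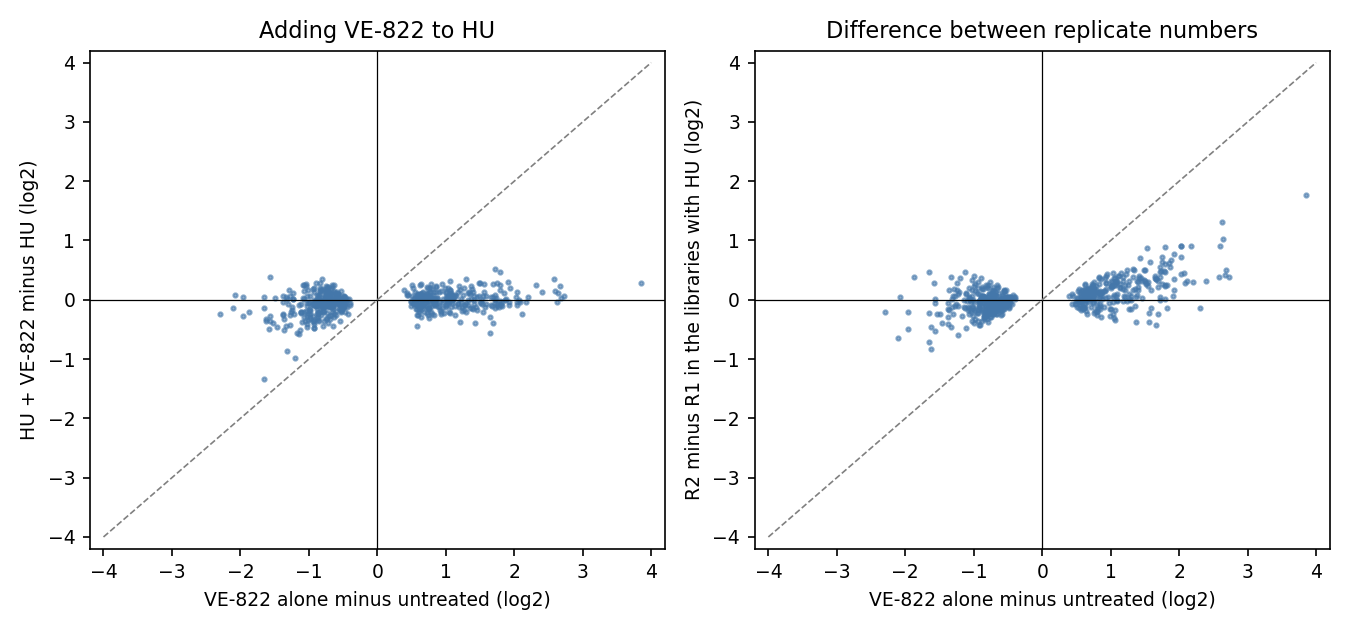
Each point is 1 of 549 genes called in VE-822 alone in both siRNAs, with the log2 change in VE-822 alone on the horizontal axis and, on the vertical axis, the change on adding VE-822 to HU (left) or R2 minus R1 in the HU libraries (right), with a dashed line of equality. The slope is 0.052 on the left, and the correlation is 0.576 on the right.

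VE-822 added to HU moved the genes called in VE-822 alone little. Over the 549 genes called in both siRNAs, the change on adding it had a slope of 0.052 on that with VE-822 alone (correlation 0.301). The 95% interval over genes, not libraries, was 0.037 to 0.068. The median size was 0.105 against 0.85, with the same sign in 57.9%. The difference between siRNAs in the VE-822 response had 0 genes called by limma (227 at an unadjusted p under 0.05, 0 by voom) and 6 lists. Matrix genes responded more in siSETD2 in all 28 (mean difference 0.46, adjusted p = 1.36e-07, 0.298 with an estimated correlation). Interferon-stimulated genes responded more in 29 of 32 (0.29, adjusted p = 5e-05, 0.725 with an estimated correlation). NF-kB genes responded more in 16 of 20 (0.23, adjusted p = 0.0263, 0.732 with an estimated correlation; 0.0504 with the block). ATF4 genes responded more in 18 of 25 (0.21, adjusted p = 0.000729, 0.298 with an estimated correlation). Heat shock genes responded less in 12 of 13 (-0.29, adjusted p = 0.0015, 0.732 with an estimated correlation). Ribosomal protein genes responded less in 44 of 45 (-0.22, adjusted p = 3.35e-07, 0.732 with an estimated correlation). Both rest in part on 1 library, untreated siSETD2 R1 (mean log2 6.71 and 7.20, against 6.11 and 6.63 in R2). The E2F G1/S list did not differ (-0.030, adjusted p = 0.424).

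Adding VE-822 to HU raised CENPA again. It rose from 6.28 ± 0.220 to 13.8 ± 1.23 FPKM in siNT (1.02, adjusted p = 0.0487 with the block). In siSETD2 it rose from 6.87 ± 0.540 to 16.1 ± 2.57 FPKM (1.11, adjusted p = 0.0212 with the block). Averaged over both siRNAs it was the only gene called without the block (1.06, SE 0.096, adjusted p = 0.00348; 1092 genes at an unadjusted p under 0.05). Of 35 splits of the 8 libraries, 2 called as many genes as the real one. Averaged and with the block 92 genes rose and 80 fell. Mitotic genes among them were PSRC1 (0.90, adjusted p = 0.0253), the mitotic regulator PIMREG (0.83, adjusted p = 0.00774), CKS2 (0.75, adjusted p = 0.0148) and HMGB2 (0.74, adjusted p = 0.00952). Others were UBE2C (0.69, adjusted p = 0.0132), the survivin gene BIRC5 (0.66, adjusted p = 0.00952) and the mitotic cyclins CCNB1 and CCNB2 (0.55 and 0.52, adjusted p = 0.0345 and 0.0132). Also risen were ATF4 (0.61, adjusted p = 0.0443), its targets DDIT3 (0.66, adjusted p = 0.0443) and PSAT1 (0.38, adjusted p = 0.0322), with DDIT4 (0.70, adjusted p = 0.0443), INSIG1 (0.73, adjusted p = 0.0311), IFIT3 (0.67, adjusted p = 0.0345) and IFIT1 (0.46, adjusted p = 0.0456). CD274 changed by -1.33 (adjusted p = 0.000583), from 8.88 ± 2.10 to 3.5 ± 1.8 FPKM in siNT and from 11.4 ± 1.23 to 3.47 ± 0.876 FPKM in siSETD2. The thrombin receptor F2RL2 changed by -0.72 (adjusted p = 0.00774), the urokinase gene PLAU by -0.69 (adjusted p = 0.0358) and the catenin ARVCF by -0.65 (adjusted p = 0.00952). The transcription factor CREB5 changed by -0.62 (adjusted p = 0.00952), endothelin EDN1 by -0.60 (adjusted p = 0.0411), CLDN4 by -0.55 (adjusted p = 0.00952) and the NF-kB cofactor NFKBIZ by -0.34 (adjusted p = 0.0253). CDKN1A stayed at 141.1 ± 11.1 FPKM in siNT and 141.5 ± 6.12 FPKM in siSETD2 (differences of 0.16 and 0.075 from HU alone), CCNE2 differed by -0.17 and -0.17, and RRM2 by -0.37 and -0.019, none past the test.

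G2/M genes were higher with VE-822 added to HU in 46 of 47 in siNT (mean 0.33, adjusted p = 3.3e-23, 0.676 with an estimated correlation; 0.47 within R1, 0.20 within R2). In siSETD2 all 47 were higher (mean 0.49, adjusted p = 7.37e-32, 0.145 with an estimated correlation; 0.60 within R1, 0.38 within R2), with 25 risen when adjusted over the list alone. Averaged, 46 of 47 were higher (mean 0.41, adjusted p = 1.66e-32, 0.21 with an estimated correlation), with 28 risen so adjusted. ATF4 genes were higher in siSETD2 in 21 of 25 (mean 0.33, adjusted p = 1.55e-06, 0.143 with an estimated correlation; 0.40 within R1, 0.25 within R2). The E2F, DP and RB family was higher there in 18 of 24 (mean 0.10, adjusted p = 0.0373, 0.145 with an estimated correlation; 0.0862 with the block). Matrix genes were lower in 24 of 28 in siNT (mean -0.19, adjusted p = 0.00965, 0.676 with an estimated correlation; -0.27 within R1, -0.12 within R2). In siSETD2 23 of 28 were lower (mean -0.19, adjusted p = 0.00288, 0.471 with an estimated correlation; -0.21 within R1, -0.17 within R2). Interferon-stimulated genes were higher in siNT in 27 of 32 (mean 0.21, adjusted p = 0.00368, 0.676 with an estimated correlation; 0.22 within R1, 0.20 within R2). Cholesterol synthesis genes were higher in 16 of 23 (mean 0.098, adjusted p = 0.0299, 0.676 with an estimated correlation; 0.057 within R1, 0.14 within R2). Mitochondrially encoded genes were lower in siSETD2 in 11 of 13 (mean -0.20, adjusted p = 0.00571, 0.669 with an estimated correlation), at -0.024 within R1 and -0.37 within R2. Ribosomal protein genes were higher in siSETD2 in 44 of 45 (mean 0.36, adjusted p = 6.59e-13, 0.471 with an estimated correlation; 0.37 within R1, 0.35 within R2). In siNT 42 of 45 were higher (mean 0.18, adjusted p = 2.35e-05, 0.825 with an estimated correlation), but only within R2 (0.38 against -0.027 within R1).

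With VE-822 added to HU in siNT, E2F G1/S targets were lower in 51 of 68 (mean -0.085, adjusted p = 0.0204, 0.856 with an estimated correlation; -0.13 within R1, -0.036 within R2). They did not differ in siSETD2 (mean 0.031, adjusted p = 0.979; -0.0003 within R1, 0.062 within R2). The difference between siRNAs was 0.12 with 58 of 68 higher (adjusted p = 0.0327, 0.891 with an estimated correlation). Without siNT R1 in HU with VE-822 the siNT mean was 0.10 (adjusted p = 0.307). The siSETD2 mean ran from -0.19 without R2 (adjusted p = 0.000119) to 0.25 without R1 in HU with VE-822 (adjusted p = 3.6e-05). p53 targets did not pass in siNT (mean -0.0056, adjusted p = 0.651; -0.054 within R1, 0.042 within R2) or in siSETD2 (-0.0028, adjusted p = 0.334; -0.047 within R1, 0.041 within R2). NF-kB genes did not pass either, with a mean of 0.030 in siNT (adjusted p = 0.312, -0.11 within R1, 0.17 within R2). In siSETD2 the mean was 0.12 (adjusted p = 0.304, 0.063 within R1, 0.17 within R2). Other differences between siRNAs were in G2/M genes (40 of 47 higher, 0.16, adjusted p = 0.00038, 0.849 with an estimated correlation) and ATF4 genes (24 of 25 higher, 0.22, adjusted p = 0.00038, 0.44 with an estimated correlation). They were also in interferon-stimulated genes (25 of 32 lower, -0.15, adjusted p = 0.0019, 0.849 with an estimated correlation) and mitochondrially encoded genes (12 of 13 lower, -0.31, adjusted p = 4.75e-05, 0.849 with an estimated correlation). Ribosomal protein genes differed (44 of 45 higher, 0.18, adjusted p = 0.00109, 0.849 with an estimated correlation). Within R2 they were no higher (0.35 in siSETD2, 0.38 in siNT). With the block 1 gene rose and 1 fell in siNT and 2 rose and 2 fell in siSETD2. In siSETD2 PIMREG rose by 0.96 (adjusted p = 0.0499), and CD274 and CLDN4 changed by -1.48 and -0.77 (adjusted p = 0.00656 and 0.0212). Limma without the block and voom called 0 within either siRNA (442 and 631 at an unadjusted p under 0.05) and 0 for the difference (103).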

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

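For the distance of the VE-822-alone libraries from all others, the test of depth was chosen before the results were seen, and the tests of a batch and of a drug effect without regard to HU were chosen after. With every library thinned to the smallest total, 659 genes were still called between VE-822 alone and untreated cells in siNT, beside 684 without thinning, so depth does not account for it. Over the 549 genes called in both siRNAs, the change correlated with R2 minus R1 in HU at 0.576 (0.446 over all genes). The sign was shared in 69.2%, as a batch of cultures or libraries would give. An effect of VE-822 that is the same with or without HU would bring the slope of the change on adding VE-822 to HU near 1, and it was 0.052. PCDH7, BMP4, MAF and MARCH4 may therefore differ by batch, or by a drug effect that depends on HU, while CD274 also changed on adding VE-822 to HU (-1.33, adjusted p = 0.000583 with the replicate block).

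For the lower E2F G1/S targets in siSETD2 in HU, the test of expression level, length and GC content was chosen before the results were seen. Those of R1 against R2 and of the difference in HU response were chosen after. The list mean of -0.12 lay at percentile 0.13 of 10000 random lists matched on these properties (median -0.060, middle 95% -0.097 to -0.027). Matched genes share much of the shift. Random lists ignore correlation between genes, so the rest may be library spread. The higher of the means within R1 and R2 was -0.076, so both had the same direction. A larger loss in HU than without it could not be told from none, since the difference in HU response had an adjusted p of 0.665 with the block and an estimated correlation. CDC6, PCNA and CHEK1 did not pass singly.

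For G2/M genes, which fell in HU and rose on adding VE-822, the test of gene-by-gene reversal was chosen before the results were seen, and that of R1 against R2 after. Between siRNAs, which share no library, the HU change and the change on adding VE-822 correlated across the 47 genes at -0.41 and -0.81 (0.08 and -0.24 over all genes), as a reversal gene by gene would give. The smallest of the 8 list means within 1 siRNA and 1 replicate number was 0.20 in the stated direction, so R1 against R2 does not account for it. CENPA was called in both steps.

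Among the exchanges of library labels, those without the block were chosen before the results were seen and those with the replicate block after. Without the block, chance could not be excluded for siSETD2 against siNT averaged over treatments, where 10 of 100 splits called at least the 17 genes of the real one and the highest other called 3882. The same held for HU averaged over both siRNAs (2 of 35 splits, 18 genes in the real one with both siRNAs pooled, 2739 in the highest other). It held as well for adding VE-822 to HU (2 of 35 splits, 5 genes in the real one, 2476 in the highest other). In the 2 latter cases the highest other split was that of R1 against R2, which the block takes up. With the block, only splits that keep R1 and R2 balanced in the 6 groups were compared, since any other is in part or wholly the block itself. For siSETD2 only the real split of 100 called as many (508 genes, 6 in the highest other). Block and restriction came from the same data, so chance is not excluded. The restriction was made after 2 of 92 splits had called as many, the real one and 1 without that balance (536). A further 8 gave no value, among them the one that called 3882 without the block. For HU and for adding VE-822 to HU, the 18 balanced splits are too few for a share under 5%, with 217 genes in the real split and 86 in the highest other for HU, and 210 and 15 for adding VE-822.

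The responses of 17 list and treatment pairs differed between siRNAs, all found by testing every list in 3 differences and none passing with an estimated correlation. In HU these were dNTP supply (-0.17, adjusted p = 0.735 with an estimated correlation), interferon-stimulated genes (0.12, 0.741), extracellular matrix genes (0.25, 0.735), heat shock genes (-0.21, 0.735) and ribosomal proteins (-0.30, 0.735). In VE-822 they were NF-kB genes (0.23, 0.732), interferon-stimulated genes (0.29, 0.725), ATF4 genes (0.21, 0.298), extracellular matrix genes (0.46, 0.298), heat shock genes (-0.29, 0.732) and ribosomal proteins (-0.22, 0.732). On adding VE-822 to HU they were E2F G1/S targets (0.12, 0.891), G2/M genes (0.16, 0.849), interferon-stimulated genes (-0.15, 0.849), ATF4 genes (0.22, 0.44), mitochondrially encoded genes (-0.31, 0.849) and ribosomal proteins (0.18, 0.849). The untreated groups enter both the HU and the VE-822 differences, so the shared signs of matrix, interferon, heat shock and ribosomal protein genes there rest in part on the same 4 libraries.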

How the results depend on the processing

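Each group had 2 libraries, R1 and R2 differed more than most groups, and the VE-822-alone libraries did not follow that pairing, so numbers of genes called moved with the error model more than fold changes did. Where a result changed, the cause was not tested unless the construction shows it. Among settings of the comparisons 509 results were unchanged, 106 moved in value, 8 changed sign, 16 gained and 28 lost a call; among named genes and other lists these were 20964, 740, 6, 483 and 848.

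With the replicate block in the 6 groups, the calls numbered 1 for siSETD2 against siNT untreated, 508 averaged, 6 in VE-822, 22 and 26 for HU in siNT and siSETD2, 2780 and 4364 for VE-822, 2 and 4 for adding VE-822 to HU, and 209 and 172 for HU and for adding VE-822 averaged over siRNAs. The E2F difference in HU response (-0.083) was gained. With the replicate block over all 8 groups they were 147 for the siRNAs averaged, 1 for HU in siSETD2, 1944 and 3421 for VE-822, and 45 and 20 for the averages over siRNAs. Fold changes are unchanged by a block, whose construction removes the R1 against R2 difference from the error.

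Without the VE-822-alone libraries, 0 genes were called for HU, for adding VE-822 and for siSETD2 averaged, where SETD2 was at -1.14 (adjusted p = 0.289). Without them and with the replicate block, the calls were 4 for HU in siNT, 72 and 56 for HU and adding VE-822 averaged and 47 for siSETD2 averaged, and the E2F difference in HU response (-0.083) was gained. With only the groups compared in the fit, calls were 326 and 0 for VE-822 in siNT and siSETD2 and 0 for both averages over siRNAs, and the E2F difference in HU response (-0.083) was gained.

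Without a filter on expression, the calls were 25, 52, 13, 31 and 13 for siSETD2 untreated, averaged, in HU, in VE-822 and in both, 19 and 19 for HU in siNT and siSETD2 with 31 for their difference, 30 for the VE-822 difference, 15 and 15 for adding VE-822 with 20 for the difference, and 46 and 25 for the averages over siRNAs. At a mean of at least 5 FPKM they were 28 for siSETD2 averaged, 292 and 882 for VE-822, 1 for adding VE-822 in siSETD2 and 2 averaged, and E2F calls in HU (-0.12, adjusted p = 0.0728) and on adding VE-822 in siNT (-0.078, adjusted p = 0.135) were lost, as was that for the difference between siRNAs (0.12, adjusted p = 0.222). A pseudocount of 0.1 gave 1 gene for siSETD2 in HU with VE-822.

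Rescaling by median ratios gave 6 genes for siSETD2 averaged (3 up and 3 down, beside 4 and 13), 380 up and 309 down for VE-822 in siNT (beside 307 and 377), and an E2F mean of -0.037 on adding VE-822 in siSETD2. Scaling to library totals gave 12 up and 5 down for siSETD2 averaged, 1 up and 9 down for HU averaged (beside 5 and 9), 2 for adding VE-822 averaged, E2F means of 0.019 untreated and 0.015 in HU with VE-822 between siRNAs, and a gained E2F difference in HU response (-0.086). limma-voom gained the same difference (-0.092). With camera and an estimated correlation, with fry, and with the block and an estimated correlation, the E2F calls in HU between siRNAs (-0.12), for HU in siNT (0.21) and siSETD2 (0.13), on adding VE-822 in siNT (-0.085) and for its difference between siRNAs (0.12) were lost.

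Leaving out 1 library in turn unbalances R1 and R2 by construction. The calls ran over 0 to 160 for siSETD2 untreated, 0 to 208 averaged, 0 to 1 in HU with VE-822, 0 to 4 and 0 to 50 for HU in siNT and siSETD2, 0 to 3 for their difference, 132 to 992 and 219 to 3325 for VE-822, 0 to 1 for adding VE-822 in siNT and for its difference, 0 to 52 for HU averaged and 1 to 3 for adding VE-822 averaged. E2F means ran over -0.17 to 0.096 between siRNAs untreated, -0.31 to 0.064 in HU, -0.22 to 0.21 in HU with VE-822, 0.069 to 0.35 for HU in siNT, -0.058 to 0.31 in siSETD2, -0.27 to 0.10 for their difference, -0.27 to 0.10 for adding VE-822 in siNT, -0.19 to 0.25 in siSETD2 and -0.10 to 0.33 for that difference. SETD2 averaged ran over -1.18 to -0.99 and lost its call without 10 of the libraries.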

Other observations

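SETD2 knockdown went with lower mitochondrially encoded transcripts and lower DARS in most libraries. All 13 mitochondrially encoded genes were lower averaged over treatments (mean -0.27, and -0.45 in HU with VE-822), within R1 and within R2, with adjusted p-values of 0.463 and 0.344 with an estimated correlation. DARS, whose level was chosen after it was seen, lay at 7.76 ± 3.72 against 22.0 ± 0.104 FPKM in untreated cells. XRCC5 and COX7A2L changed by -0.86 and -0.59, and an siRNA that also lowers unrelated transcripts would look the same, which 1 siRNA cannot tell from an effect of SETD2. With the VE-822-alone libraries left out no gene was called on average, SETD2 included (adjusted p = 0.289), although its fold change of -1.14 was as large as before, and the cause of the lost calls was not tested.

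ATR activity was not measured in these data. CD274, which encodes PD-L1, had a lower mean with VE-822 than without it, alone or added to HU, in both siRNAs. On adding VE-822 to HU, CD274 passed only with the block. It went from 8.63 ± 1.51 to 2.00 ± 0.288 FPKM in VE-822 alone and from 8.88 ± 2.10 to 3.5 ± 1.8 FPKM on adding VE-822 to HU in siNT, and from 11.4 ± 1.23 to 3.47 ± 0.876 FPKM on adding it in siSETD2. Most other genes of the VE-822-alone response did not do so, with a slope of 0.052 between both settings. A batch in those libraries and an effect of VE-822 that depends on HU could both give this.

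NF-kB and cytokine genes were higher after 4 h of HU beside p53 targets. All 20 NF-kB genes were higher averaged over siRNAs (mean 0.53, adjusted p = 0.17 with an estimated correlation), and IL6, CXCL8, CCL2 and TNFAIP3 passed with the block. On adding VE-822 to HU, G2/M genes were higher in siNT (mean 0.33, adjusted p = 0.676 with an estimated correlation) and in siSETD2 (0.49, 0.145), while p53 targets did not pass (-0.0056 and -0.0028). NF-kB genes did not pass either, at -0.11 within R1 and 0.17 within R2 in siNT and 0.063 and 0.17 in siSETD2. In VE-822 alone neither G2/M genes (0.074 and 0.11) nor p53 targets (-0.23 and -0.22) passed, and this was not tested against the change on adding VE-822 to HU. The reversal correlated gene by gene between siRNAs at -0.41 or below and held within each replicate number at 0.20 or more, and its mechanism was not tested.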
